A study of Homo sapiens with 10 samples.

How the data were processed

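RNA sequencing was done on single-cell clones of the lymphoma cell line labelled U2392, 6 samples with wild-type and 4 with R475C DDX3X. Per the labels' protocols, cells received Cas9 and a guide RNA on a plasmid together with a double-stranded template carrying R475C or, for the controls, the wild-type sequence, plus silent changes at the PAM and for a SpeI site, and were cloned from single cells. Libraries were made from poly(A)-selected RNA with a NEBNext module and sequenced on an Illumina HiSeq instrument. Transcripts without a poly(A) tail, such as most canonical histone transcripts, are therefore mostly lost.

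The authors deposited 1 table of raw read counts per gene, whole numbers that were not normalized, for all 10 samples. Per the submitters' processing notes, the tools were cutadapt 1.10 (adapter trimming), STAR 2.6.0c (alignment) and featureCounts (counting, version not given). Genome build, annotation and strand setting are not given in the sources used here. All 58721 versioned gene IDs of the table equal those of GENCODE release 29 (GRCh38), which supplied coordinates and gene types, and 58252 IDs had a current symbol in the name table. No row failed to name a gene and no column belonged to an unlisted sample. Genes that overlap can share reads under some counting settings: SENP3-EIF4A1 and EIF4A1, which share exons, held a mean of 594.3 and 557 CPM, and TYMS and ENOSF1, which overlap on opposite strands, held 256 and 241 CPM, and BACH2, MTHFD1, PDIA6 and P4HB each overlap a gene on the opposite strand that also passed the test, as do C8orf88 and NECAB1. Of the 65 named genes 21 overlap another tested gene.

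Samples were grouped by the genotype and replicate number in their titles. Total counts ran from 8928539 to 53779005, and mitochondrial transcripts took 3.98% to 5.62% of them. The shallowest library was R475C replicate 4. In the 21 pairs of samples within a group, the chi-square of the counts per gene ran from 11.2 to 91.7, far above sampling noise, so no library was a copy of another of its group, and each counted as 1 replicate. By correlation of log2 CPM the samples lay closest in pairs. In wild-type these were replicates 1 and 4 (0.9764), 2 and 6 (0.9851) and 3 and 5 (0.981). In R475C they were replicates 1 and 3 (0.9823) and 2 and 4 (0.9635). Whether paired samples share a clone was not tested, and if they do, the p-values are too small.

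Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with its defaults of a minimum count of 10 and a minimum total of 15, glmQLFit and glmQLFTest with genotype as the only term, two-sided) on the counts as deposited. Benjamini-Hochberg adjustment ran over the 17045 genes kept, with an adjusted p threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the test's F value. The common biological coefficient of variation was 0.282. Log2 CPM values used a prior count of 1. DDX3X was also tested by exact permutation of the group labels. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided) against all other tested genes, adjusted over the 36 of 40 lists with at least 5 tested members, and again with the correlation estimated per list and with fry. The 40 lists, the main test, the alternatives and the rule for named genes were fixed before the data were examined.

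Named genes were chosen as follows. DDX3X, MYC, BCL6, CD38, MS4A1, BCL2, ATF4, DDIT3 and EIF4A1 were given whatever their values. The 12 largest rises and 12 largest falls were taken among protein-coding genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out immunoglobulin and T-cell receptor segments and unnamed loci. In each list described, up to 4 members past the threshold with the smallest p were given. Further members of the B-cell lists, H2BC5, MYBL1, P4HB, ENOSF1, ATP6V1C2, ENSG00000226455, EPCAM, FN1, LUM, DCN and the mitochondrial transcripts were named after their values were seen.

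The test was checked on simulated counts drawn from the real means, dispersions and library sizes of 6 against 4 libraries, with 200 genes changed. It recovered 26% of genes changed 1.5-fold, 66% of those changed 2-fold, 92% of those changed 4-fold and 96% of those changed 8-fold. Of 142 genes called, 2 had not been changed. With independent genes camera called no list when none was shifted and found the 1 list that was.

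The alternatives were RLE, upper-quartile and library-size scaling, no low-count filter or at least 1 CPM in at least 4 samples, the robust fit, the replicate number as a block, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma-voom, an adjusted p of 0.01, and leaving out each sample in turn. Added after seeing the data were the 2 sets of samples as a covariate, each set alone, per-library length and GC trends (loess span 0.5) as offsets, and an exact permutation of list means. No replicate block entered the main test, since the labels do not tie equal numbers to each other. Levels of Y-linked genes and XIST are not reported.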

Results

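Poly(A)-selected RNA was sequenced from single-cell clones of a human lymphoma cell line, labelled U2392, to compare clones carrying the R475C change in DDX3X with clones edited with a wild-type template. DDX3X encodes a DEAD-box RNA helicase, an enzyme that unwinds RNA structure and takes part in the start of translation, and it is recurrently mutated in B-cell lymphomas. Both sets of clones had been through the same Cas9 editing, in which the template also carried silent changes, so the wild-type group is a control for the editing itself. The series held 10 samples, of which 6 were wild-type and 4 were R475C. Wild-type replicates 1 to 6 held 35454145, 28556187, 21533734, 24827546, 18191556 and 33268421 counts over all genes. R475C replicates 1 to 4 held 19640974, 53779005, 33634104 and 8928539. The labels do not say which replicates are separate clones or separate cultures of 1 clone, so the p-values measure only the spread between these samples, which may be partly technical. Within each genotype the samples lay closest in pairs, and samples that share a clone would not be independent. Levels are given as CPM, a gene's count relative to the library size scaled by edgeR's TMM factors, as mean ± SD with n = 6 for wild-type and n = 4 for R475C.

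The first question was whether the edited gene itself changed in level. DDX3X (ENSG00000215301.10; chromosome X, 41333284 to 41364472, plus strand, GRCh38) was higher in R475C, at 932 ± 126 CPM against 421 ± 70.5 CPM in wild-type, a log2 fold change of 1.15 (SE 0.13; 2.21-fold). The 4 R475C samples lay between 753.9 and 1047 CPM and the 6 wild-type samples between 357.3 and 550.8 CPM, so the groups did not overlap. The rise passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00194), and an exact two-sided permutation test over the 210 arrangements of the samples gave p = 0.00476, the smallest it allows. Both tests take the samples as independent. The codon of the edited residue lies at 41346336 to 41346338 on chromosome X, in the coding sequence of exon 13 of 17 of transcript ENST00000644876.1 in GENCODE release 29. A change of 1 residue need not alter the transcript level, so this level does not serve as a check of the labels. No tested gene within 2 Mb passed the test, and USP9X and CASK, which flank DDX3X, had log2 fold changes of 0.16 (SE 0.10) and 0.21 (SE 0.13).

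**Figure D1:**
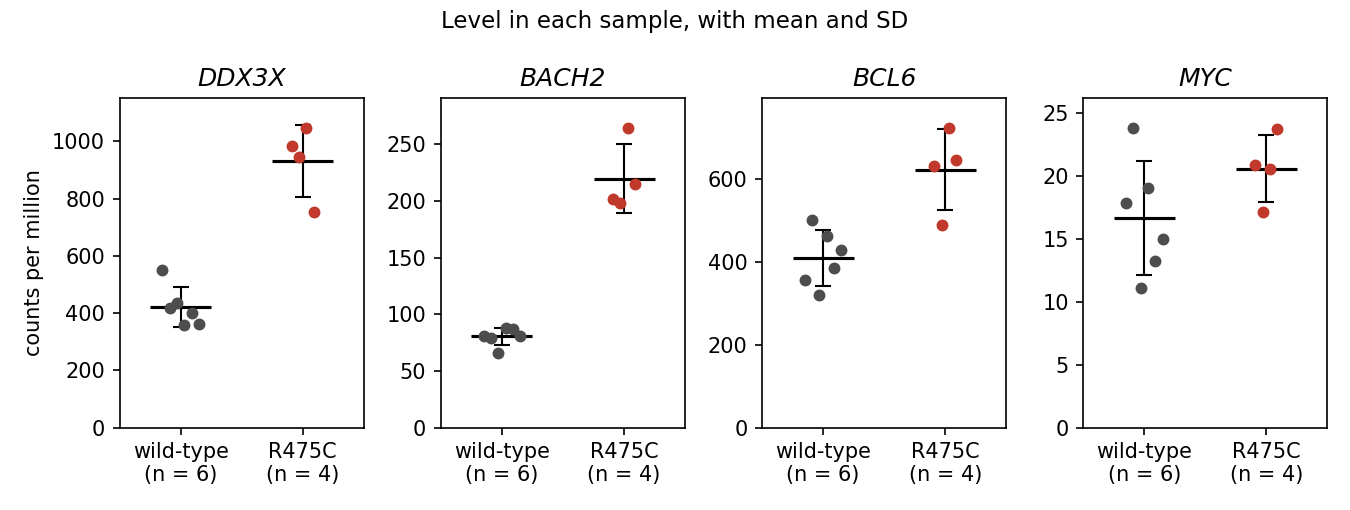
CPM of DDX3X, BACH2, BCL6 and MYC in each sample (points; grey, 6 wild-type samples; red, 4 R475C samples), with the group mean (line) and SD (bars); the linear axes start at 0. All R475C samples lie above all wild-type samples for DDX3X (753.9 to 1047 against 357.3 to 550.8 CPM) and BACH2, and the groups overlap for BCL6 and MYC.

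The second question was which other transcripts differed between the genotypes. The largest rises were in zinc-finger genes, with ZNF486 at 6.65 ± 1.46 CPM in R475C against 0.264 ± 0.190 in wild-type (log2 fold change 4.61, SE 0.50, adjusted p = 0.00146), followed by ZNF831 (4.07, SE 0.40) and ZNF93 (3.35, SE 0.72). ZNF93 was at 2.169 and 2.264 CPM in R475C replicates 1 and 3 against 1.28 and 0.8386 in wild-type replicates 1 and 4, with no call among these alone. R475C replicates 2 and 4 held 7.485 and 9.718 CPM, and the other wild-type samples at most 0.4181. ZNF880 (2.13) and ZNF628 (1.39) rose as well. ZNF628 went from 12.5 ± 1.49 to 32.9 ± 4.10 CPM. Among well-expressed genes BACH2, a transcriptional repressor that holds B cells back from plasma-cell differentiation, rose from 80.5 ± 7.89 to 219.8 ± 30.7 CPM (log2 fold change 1.45, SE 0.10, adjusted p = 1.43e-04), the smallest p of any gene tested. An unnamed locus that it overlaps on the other strand, ENSG00000226455, rose as well (1.29). HMCES, which binds abasic sites in single-stranded DNA, rose from 125 ± 38.0 to 293.6 ± 40.8 CPM (1.23, SE 0.19). CD84, a SLAM-family receptor of lymphocytes, rose by 1.57 (SE 0.27) and EGR3, an immediate-early transcription factor, by 1.30 (SE 0.21). FAM50B (1.98), SLC4A11 (1.82) and NAALADL1 (1.33) complete the 12 largest rises, each at under 3.5 CPM in R475C.

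The 12 largest falls had log2 fold changes between -3.22 and -4.86, and all came from genes at about 20 CPM or less in wild-type. MARCKS, an actin-binding substrate of protein kinase C, fell from 20.4 ± 7.43 to 1.94 ± 1.37 CPM (log2 fold change -3.44, SE 0.52, adjusted p = 0.00734). CREB3L1, a transcription factor of the endoplasmic reticulum membrane, fell from 17.5 ± 6.0 to 1.71 ± 0.891 CPM (-3.34, SE 0.39). SLC25A43 (-4.20, SE 0.52), a mitochondrial carrier protein, and XK (-4.44, SE 0.53), which encodes the membrane protein of the Kx blood group, lie on chromosome X. KBTBD12 fell from 11.2 ± 7.80 to 0.445 ± 0.509 CPM (-4.86, SE 0.88). TP63, a transcription factor, fell from 5.01 ± 3.64 to 0.481 ± 0.356 CPM (-3.23, SE 0.67). FAM171B, CXXC4, LIN7A and MGAT4A had log2 fold changes between -3.22 and -3.90. LIN7A was at 0.7566 and 0.6789 CPM in wild-type replicates 1 and 4, at 4.077 to 6.655 in the other wild-type samples, and at most 0.5435 in R475C. It was not called among wild-type replicates 1 and 4 and R475C replicates 1 and 3 alone. C8orf88 (-4.61) and NECAB1 (-4.29) share 772 bases on opposite strands of chromosome 8, and their falls cannot be fully separated because the strand setting of the counting is not given in the sources used here. In wild-type replicates 1 and 4 C8orf88 was at 0.4365 and 1.438 CPM and NECAB1 at 1.31 and 1.118 CPM. The other wild-type samples held at least 4.298 and 4.438 CPM. Neither gene was called among wild-type replicates 1 and 4 and R475C replicates 1 and 3 alone.

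**Figure D2:**
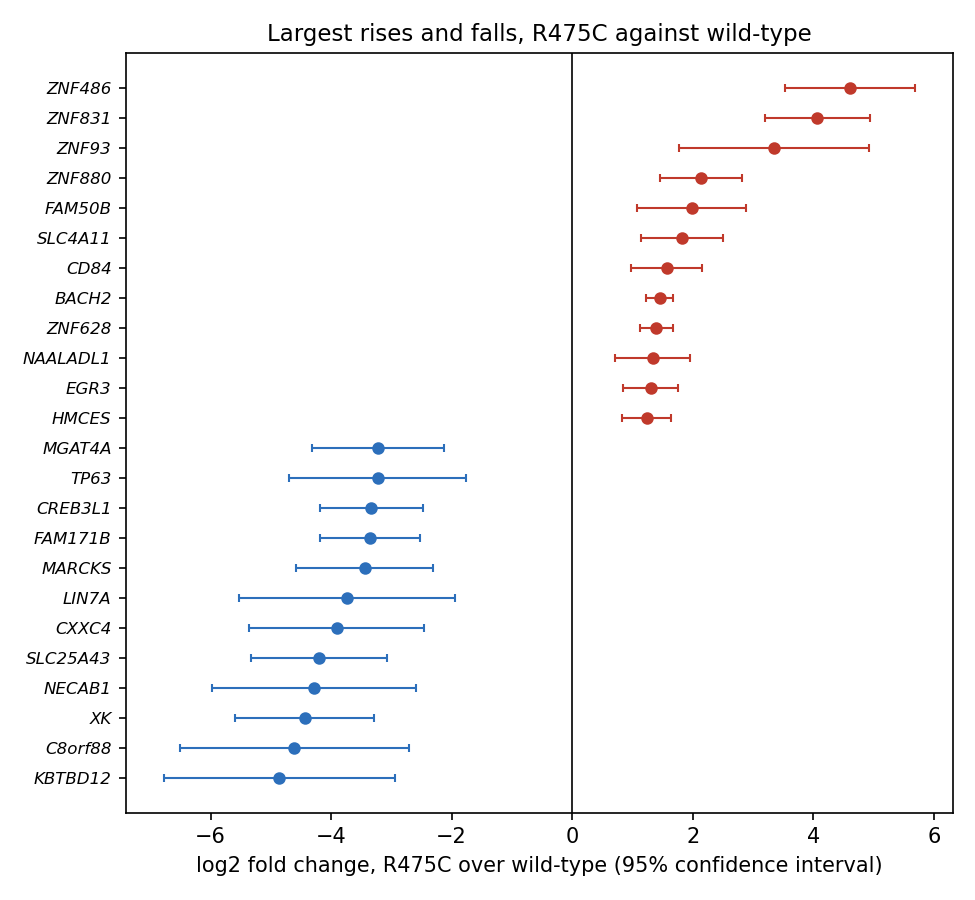
Log2 fold change of R475C over wild-type (horizontal axis, points) with its 95% confidence interval (bars) for the 12 largest rises (red) and 12 largest falls (blue) among protein-coding genes whose groups do not overlap. The rises run from 1.23 (HMCES) to 4.61 (ZNF486) and the falls from -3.22 (MGAT4A) to -4.86 (KBTBD12).

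Over all 17045 genes tested, 419 differed (adjusted p under 0.05), 223 higher and 196 lower in R475C, or 2.46% of those tested. At least a 2-fold change was seen in 122, of which 33 were higher and 89 lower. An unadjusted p under 0.05 was reached by 2951 of the 17045 genes, and DESeq2 called 1156. Counts of list members at these thresholds are to be read against those totals. In 395 of the 419 the groups did not overlap, and the same was true of 1042 of all genes tested (6.11%, against 0.952% by chance). By type, 384 were protein-coding, 2 were immunoglobulin or T-cell receptor segments and 26 were unnamed or LINC loci. The count depended on single libraries: it was 794 without wild-type replicate 1, 284 without wild-type replicate 4, and between 142 (without R475C replicate 3) and 260 (without wild-type replicate 2) without any 1 of the other samples. Of the 419 calls, 116 held in all 10 of these fits and 226 in at most 4. Among the genes named here, EZH2, B2M, SDHA, CHAF1A and P4HB held in 1 of the 10, and ZNF93, LIN7A, RPLP0, MRPS15, EIF4G3, SLC7A1, PDIA6, HSP90B1, ERN1, DDB2, CCR7, LPP, MYBL1 and H2BC5 in 2. BCL6, NAALADL1, MTHFD1, CCNE2 and ISG20 held in 3, and FAM50B, TP63, RPS18 and SLBP in 4.

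Genes of the B-cell differentiation programme were examined as lists fixed before the data were examined. Of 30 tested genes typical of activated B cells and plasma cells, 23 had a lower level in R475C and the median log2 fold change was -0.42. XBP1, the transcription factor that drives secretory differentiation, fell from 246.5 ± 31.3 to 134 ± 7.40 CPM (log2 fold change -0.87, SE 0.11, adjusted p = 0.00216). ELL2, an elongation factor used in immunoglobulin secretion, fell from 16.8 ± 3.06 to 7.61 ± 1.07 CPM (-1.14, SE 0.16, adjusted p = 0.00594). These were the 2 members past the test over all genes, and 12 were lower when adjusted over the list alone, among them SDC1 (-1.38), BATF (-1.22), TNFRSF13B (-1.01), DERL3 (-0.96) and CD27 (-0.55). PRDM1, the master regulator of plasma cells, was at 6.73 CPM against 10.7 CPM (-0.66, adjusted p = 0.264) and IRF4 at 308.7 against 403.7 CPM (-0.39, adjusted p = 0.256), neither past the test. The list was called lower by camera (adjusted p = 3.55e-08) and the call held with an estimated correlation (adjusted p = 0.0341).

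In the list of germinal centre B-cell genes 5 of 28 rose, 1 fell and 22 did not pass the test. The rises were BACH2, KLHL6 (log2 fold change 0.85, SE 0.17), LPP (1.38, SE 0.30), MYBL1 (0.75, SE 0.17) and BCL6. Loci on the other strand of BCL6, ENSG00000228804 (0.77) and ENSG00000285938 (1.09), and of LPP, LPP-AS2 (0.97), were higher as well but not called. The 134 tested genes of chromosome 3 from 180 Mb onward, BCL6 among them, had a median log2 fold change of 0.04. Whether some of these rises share a local cause was not tested, so they may not be separate changes. BCL6, the repressor that maintains the germinal centre state, was at 622.5 ± 97.9 CPM against 409 ± 68.1 CPM in wild-type (0.61, SE 0.14, adjusted p = 0.0437). Of the 10 fits that each left out 1 library, the call was lost in 7 for BCL6, 8 for LPP, 8 for MYBL1, 4 for KLHL6 and 9 for EZH2, while that of BACH2 held in all 10. EZH2, a histone methyltransferase of dividing germinal centre cells, fell by 0.32 on the log2 scale (SE 0.07, adjusted p = 0.0358). Adjusted over the list alone, 10 members were higher and 1 was lower. The list median was 0.11, called higher by camera (adjusted p = 9.33e-05) but not with an estimated correlation (adjusted p = 0.384). Among pan-B-cell identity genes 1 of 22, TCF3 (0.52, SE 0.10, adjusted p = 0.0219), rose and the list was not called (adjusted p = 0.0717). MS4A1, which encodes CD20, was at 1746 ± 342 CPM against 1641 ± 270 (0.09, adjusted p = 0.817), and CD38 had a log2 fold change of -0.25 (adjusted p = 0.557).

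In the B-cell receptor signalling list MALT1, a scaffold and protease of the NF-kB pathway, rose from 231.8 ± 21.5 to 364 ± 28.6 CPM (log2 fold change 0.65, SE 0.09, adjusted p = 0.00474), and PRKCB, the kinase upstream of it, fell from 89.7 ± 14.4 to 48.8 ± 10.6 CPM (-0.88, SE 0.16, adjusted p = 0.0178). The other 34 members did not pass and the list was not called (adjusted p = 0.302). Adjusted over the list alone 4 members were higher and 1 lower, as by DESeq2, and with 1 surrogate variable 7 were higher and 1 lower. Of 32 NF-kB target genes 1 passed, CCR7, a chemokine receptor, with a log2 fold change of -2.24 (SE 0.51, adjusted p = 0.0441), and the list was not called (adjusted p = 0.154). In the interferon list ISG20 rose (0.61, SE 0.12) and in the MHC class I list B2M, the light chain of the complex, fell from 178 ± 17.9 to 128 ± 17.2 CPM (-0.47, SE 0.11, adjusted p = 0.0430), with neither list called (adjusted p = 0.275 and 0.0915). None of 16 MHC class II genes and none of 15 BCL2-family genes passed. BCL2 itself was at 1124 ± 315 against 1479 ± 255 CPM (-0.40, SE 0.18, adjusted p = 0.278).

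Canonical histone genes, transcribed during S phase, were lower as a group. Of 25 tested, 22 had a lower level in R475C, with a median log2 fold change of -0.76. H4C9 fell from 18.6 ± 2.38 to 5.88 ± 0.646 CPM (log2 fold change -1.66, SE 0.14, adjusted p = 4.22e-04), H2BC12 from 10.9 ± 1.41 to 3.41 ± 0.635 CPM (-1.66, SE 0.17), H3C10 by 1.5 (SE 0.22) and H2BC11 by 1.55 (SE 0.27) on the log2 scale. With H2BC5 these were the 5 members past the test, against 10 adjusted over the list alone. None passed as higher by edgeR or DESeq2, and 1 was higher at an unadjusted p under 0.05. The list was called by camera (adjusted p = 5.28e-09) and the call held with an estimated correlation (adjusted p = 0.0488). Most canonical histone transcripts end without a poly(A) tail, so these libraries hold only a small part of them, and near-identical copies can share reads. Summed over the histone genes of the list, the level was 85.6 ± 19.6 CPM in R475C and 168 ± 49.4 CPM in wild-type, without overlap (67.1 to 105 against 117 to 252 CPM).

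**Figure D3:**
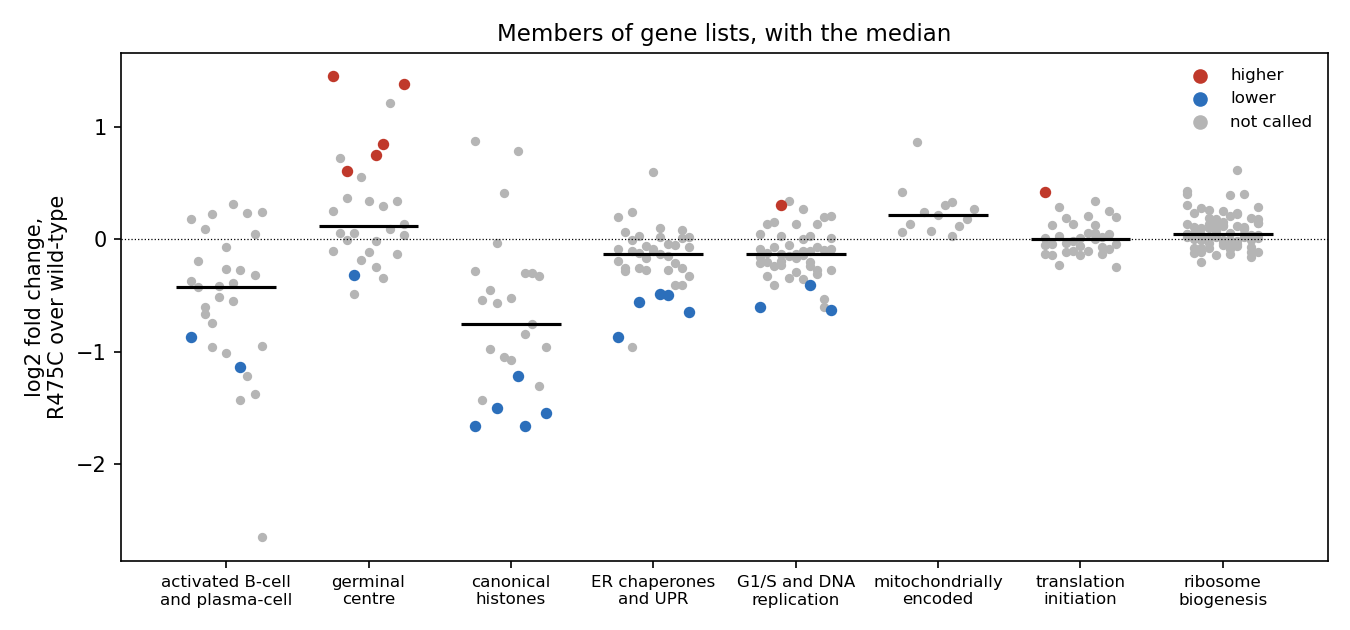
Log2 fold change of R475C over wild-type (vertical axis) for each tested member of 8 gene lists (points; red, higher; blue, lower; grey, not past the test), with the list median (line). The medians are -0.42 for activated B-cell and plasma-cell genes, 0.11 for germinal centre genes and -0.76 for canonical histones, and those of translation initiation factors and ribosome biogenesis genes lie within 0.05 of 0.

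Among G1/S and DNA replication genes 3 of 49 fell and 1 rose, while 19 were lower and 3 higher at an unadjusted p under 0.05, and 8 fell and 1 rose with 1 surrogate variable. SLBP, which binds the stem-loop at the end of histone transcripts, fell from 332.5 ± 28.1 to 250.6 ± 11.7 CPM (log2 fold change -0.41, SE 0.08, adjusted p = 0.0272), CCNE2, a cyclin of S-phase entry, by 0.63 (SE 0.15), and TYMS, the enzyme that makes thymidylate, from 296.4 ± 16.6 to 195 ± 31.6 CPM (-0.60, SE 0.10, adjusted p = 0.0121). TYMS overlaps ENOSF1 on the other strand, which fell by 0.52. CHAF1A, a histone chaperone, rose by 0.30 (SE 0.07). The list median was -0.14, called lower by camera (adjusted p = 3.13e-04) but not with an estimated correlation (adjusted p = 0.700). None of 52 G2/M and mitotic genes passed (list adjusted p = 0.999). CDKN1A, the cell-cycle inhibitor p21, fell from 125 ± 36.6 to 29.7 ± 18.2 CPM (-2.09, SE 0.38, adjusted p = 0.0163) and DDB2, a DNA-damage recognition protein, by 0.42 (SE 0.09).

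Endoplasmic reticulum chaperones and unfolded protein response genes had 5 of 40 members lower and none higher by edgeR, 7 lower and 1 higher by DESeq2, and 10 lower and 2 higher at an unadjusted p under 0.05. Besides XBP1, which is also in the plasma-cell list, those called by edgeR were PDIA6 (log2 fold change -0.50, SE 0.10), which overlaps ATP6V1C2 on the other strand (-0.51), HSP90B1 (-0.56, SE 0.12), ERN1 (-0.65, SE 0.15), the stress sensor that splices XBP1 transcripts, and P4HB, from 568.6 ± 83.5 to 404 ± 34.5 CPM (-0.49, SE 0.12, adjusted p = 0.0472). Camera called the list lower (median -0.13, adjusted p = 2.35e-04) but not with an estimated correlation (adjusted p = 0.491). ATF4, the transcription factor of the integrated stress response, was at 282 ± 10.4 against 338 ± 59.4 CPM (-0.26, adjusted p = 0.322), and DDIT3 had a log2 fold change of 0.05 (adjusted p = 0.946). Of 33 ATF4 and stress-response targets 1 passed, the amino acid transporter SLC7A1, which rose (0.38, SE 0.09), although 6 were lower and 1 higher at an unadjusted p under 0.05, DESeq2 called 2 lower and 1 higher, the list median was -0.25, and camera called the list lower (adjusted p = 0.0250, and 0.726 with an estimated correlation). None of 30 heat-shock and cytosolic chaperone genes passed, and the list was not called (adjusted p = 0.458).

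DDX3X acts in translation, and few genes of that machinery passed the test, which recovered 26% of simulated 1.5-fold changes. Of 35 translation initiation factors 1 passed, EIF4G3, a scaffold of the cap-binding complex, which rose by 0.42 (SE 0.09, adjusted p = 0.0414), and the list median was 0.00 (adjusted p = 0.729). EIF4A1, the initiation helicase, was at 533 ± 55.7 against 573 ± 69.0 CPM (-0.10, adjusted p = 0.676). It shares exons with a read-through transcript, SENP3-EIF4A1, counted at nearly the same level. None of 33 other DEAD-box helicases, 14 elongation and release factors or 75 ribosome biogenesis genes passed, and none of these lists was called (adjusted p = 0.776, 0.710 and 0.107). Of 78 cytosolic ribosomal protein genes, RPS18 rose from 309 ± 28.1 to 421.3 ± 35.4 CPM (0.45, SE 0.09) and RPLP0 fell from 1142 ± 102 to 892 ± 42.7 CPM (-0.36, SE 0.08), while 12 were higher and 1 lower at an unadjusted p under 0.05. The list median was 0.04, called higher by camera (adjusted p = 0.0463, and 0.726 with an estimated correlation). Stress granule and P-body components had a median of 0.09 with none of 37 past the test (adjusted p = 0.0300, and 0.700 with an estimated correlation). MYC was at 20.6 ± 2.69 against 16.7 ± 4.54 CPM (0.30, SE 0.19, adjusted p = 0.476), and of 47 MYC-activated genes 1, MTHFD1, fell (-0.40, SE 0.08) without a call for the list (adjusted p = 0.0915).

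Mitochondrial genes of the 2 genomes had medians of opposite sign. All 13 transcripts encoded in mitochondria had a higher level in R475C, with a median log2 fold change of 0.22, and none passed over all genes, while 4 did when adjusted over the list alone, MT-ND4L, MT-ND5, MT-ND4 and MT-CO1. Nuclear-encoded oxidative phosphorylation genes had a median of -0.12, with 1 of 76 past the test, SDHA, which fell from 85.8 ± 14.7 to 59.9 ± 1.58 CPM (-0.52, SE 0.12, adjusted p = 0.0490). Camera called both lists (adjusted p = 4.61e-04 and 1.41e-04), and neither with an estimated correlation (adjusted p = 0.491 and 0.726). The mitochondrial share of counts ran from 4.54% to 5.62% in R475C samples and from 3.98% to 4.93% in wild-type samples. Mitochondrial ribosomal protein genes had a median of -0.08 with MRPS15 lower and 16 lower against 0 higher at an unadjusted p under 0.05 (MRPS15 -0.43, SE 0.10; list adjusted p = 0.00598, and 0.726 with an estimated correlation). With no member past the test, camera also called snoRNA host genes higher (median 0.27), and cholesterol synthesis (-0.22), proteasome (-0.15) and glycolysis genes (-0.12) lower, with adjusted p = 2.32e-04, 0.00367, 0.00517 and 0.0463. With an estimated correlation these were 0.491, 0.726, 0.726 and 0.700.

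Markers of other cell types were examined because a line can carry other cells. No erythroid or megakaryocyte marker was high enough to be tested, and none of the 4 T-cell and NK-cell markers and 3 myeloid markers tested passed. Of 7 fibroblast, epithelial and endothelial markers none passed, with a median log2 fold change of -1.30 (camera adjusted p = 0.0485, and 0.491 with an estimated correlation). Of the 7, 6 were lower. The most abundant was EPCAM, at 24.6 against 26.7 CPM (-0.11). FN1, at 1.79 ± 0.926 against 6.47 ± 4.46 CPM (-1.91, SE 0.58, adjusted p = 0.111), and LUM, at 0 against 1.17 ± 1.28 CPM, were not called by edgeR with genotype as the only term, but were called lower by DESeq2 and by edgeR with 1 surrogate variable or with the 2 sample sets as covariate, the last of which also called DCN lower. Of all 17045 genes tested, 2951 had an unadjusted p under 0.05 and DESeq2 called 1156. In the lists where edgeR called no member, the members at an unadjusted p under 0.05, with those called by DESeq2 in brackets, numbered 6 (1) of 16 MHC class II genes, 4 (2) of 15 BCL2-family genes, 1 (0) of 52 G2/M and mitotic genes, 2 (1) of 30 heat-shock genes and 3 (1) of 33 other DEAD-box helicases. They numbered 0 (0) of 14 elongation and release factors, 5 (0) of 75 ribosome biogenesis genes, 4 (1) of 37 stress granule components, 6 (1) of 13 mitochondrial transcripts, 7 (0) of 22 snoRNA host genes and 4 (2) of 24 cholesterol synthesis genes. For proteasome, glycolysis, T-cell and NK-cell, myeloid, and fibroblast, epithelial and endothelial lists they were 4 (1) of 31, 4 (0) of 25, 2 (0) of 4, 0 (0) of 3 and 2 (2) of 7. For WNT target genes, aminoacyl-tRNA synthetases, splicing factors and hypoxia-induced genes they were 4 (3) of 11, 3 (0) of 22, 4 (0) of 34 and 1 (0) of 22. In all, camera called 16 of 36 lists with at least 5 tested members, 11 lower and 5 higher. With an estimated correlation 2 remained, canonical histones and the activated B-cell and plasma-cell genes. Further lists not called by camera were aminoacyl-tRNA synthetases (median -0.11, adjusted p = 0.0531), splicing factors (-0.04, 0.314), hypoxia-induced genes (-0.07, 0.314), MHC class II genes (0.10, 0.296), BCL2-family genes (-0.08, 0.389), immediate-early genes (0.01, 0.484) and WNT target genes (0.16, 0.604).

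Within both genotypes the samples fell into 2 sets that do not follow the edit. Wild-type replicates 1 and 4 and R475C replicates 1 and 3 lay on one side of the first principal component (34.1% of the variance) and the other 6 samples on the other. Genes of chromosome 10 had a median log2 level, relative to the mean of the sample's own group, of 0.50, 0.49, 0.38 and 0.39 in those 4 samples and between -0.37 and -0.21 in the other 6. Genes of chromosome 21 had 0.36, 0.39, 0.31 and 0.34 in the 4 and between -0.30 and -0.16 in the others. On chromosome 3 the same 2 sets differed in the windows of 20 Mb from 100, 120 and 140 Mb, by a median log2 of 0.30, 0.52 and 0.50 in wild-type and 0.30, 0.55 and 0.58 in R475C. Within the 4 samples DDX3X had a log2 fold change of 1.17 (SE 0.20, adjusted p = 0.0120), and within the other 6 of 1.07 (SE 0.12, adjusted p = 0.00307), each by edgeR's quasi-likelihood test. Within the 4 samples 306 genes differed and within the other 6 samples 461. Of the 419 genes called over all samples, 94 and 212 passed the test within these 2 sets. Within the 4, the fit set wild-type replicates 1 and 4 against R475C replicates 1 and 3, and both are closest pairs. R475C replicates 2 and 4, in the other 6, are a closest pair as well. If paired samples share a clone, the p-values within the sets are too small and the counts too high.

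**Figure D4:**
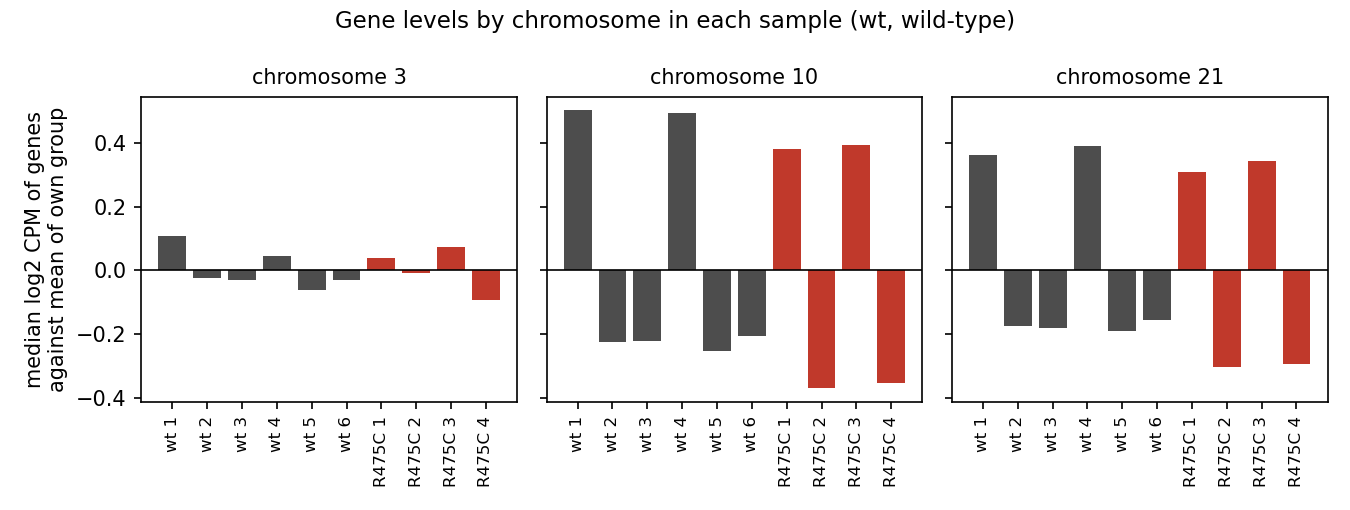
Median over the genes of chromosomes 3, 10 and 21 of the log2 CPM in each sample relative to the mean of its own group (vertical axis; grey, 6 wild-type samples; red, 4 R475C samples). On chromosomes 10 and 21 wild-type replicates 1 and 4 and R475C replicates 1 and 3 stand above 0.30 and the other 6 samples below -0.15, while chromosome 3, where windows of the long arm differ between these sets, stays within 0.11 of 0 as a whole.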

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

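No test in this part was chosen after its result was seen. For each of the 65 named genes the log2 CPM values of each group, and the library totals, were examined for 1 sample lying far from the rest, measured as the gap to the nearest other sample divided by the range of the group. Of 132 groups of values, 6 held such a sample, and 6.6 are expected by chance at 1 in 20, so no pattern is drawn from them. Among the 6 wild-type samples, BACH2 was low in replicate 3 (ratio 0.647; 6.04 against a median of 6.34 in the others) and ZNF628 was low in replicate 1 (ratio 0.785; 3.26 against 3.73). Among the 4 R475C samples, replicate 4, the shallowest library, was low for MRPS15 (ratio 0.841; 6.20 against 6.34) and XBP1 (ratio 0.845; 6.95 against 7.10). H3C10 was low in R475C replicate 1 (ratio 0.869; 1.11 against 1.55) and ISG20 in R475C replicate 2 (ratio 0.878; 6.02 against 6.37). The low R475C values of XBP1, MRPS15 and H3C10 lie further from wild-type than the other R475C samples do, while that of ISG20 lies nearer. BACH2, XBP1, ZNF628 and H3C10 passed the test in each of the 10 fits that left out 1 sample, MRPS15 in 2 and ISG20 in 3 of them.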

How the results depend on the processing

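The tests with the 2 sets of samples, the length and GC offsets and the exact permutation of list means were chosen after the data were seen. DDX3X stayed higher and past the threshold in every setting but the replicate block, with log2 fold changes from 1.055 (length and GC offsets) to 1.227 and adjusted p from 8.29e-13 to 0.0120 (1.085 to 1.227, adjusted p up to 0.00970, without any 1 sample). With the replicate block it was 1.088 (adjusted p = 0.0543), and edgeR called 0 genes and 0 of at least 2-fold, with 1961 at an unadjusted p under 0.05. Within-group deviations correlated by a mean of 0.00379 for equal replicate numbers and -0.00323 for unequal ones, so the block takes degrees of freedom with no pairing to gain from. Against 419 genes (122 of at least 2-fold), 1 surrogate variable gave 1197 (300), DESeq2 1156 (306) and the 2 sample sets as covariate 1128 (301), and the cause was not tested. They kept 100%, 99.3% and 100% of the 419 calls. An adjusted p under 0.01 left 80 (35) by construction. Without 1 sample the counts ran from 142 (54; without R475C replicate 3) to 794 (212; without wild-type replicate 1), with 284 (97) without wild-type replicate 4 and 260 (102) or fewer without any 1 of the others. The 4 samples that stand apart alone gave 306 genes (257) and the other 6 alone 461 (218), the cause not tested, and 36.0% of the calls in the 4 were higher against 53.2% in all 10. Both of these fits compare closest pairs of samples, so their counts hold only if paired samples are independent. The other settings gave 357 to 496 genes, and no scaling moved the median of all genes by as much as 0.03. Fry in either direction, which takes members moving either way and does not set them against other genes, called 17 lists. It called 10 that camera did not and lost 9. Among the 10 were B-cell receptor signalling (adjusted p = 1.485e-05), pan-B-cell identity (0.001172), MHC class II (0.001522), BCL2-family (0.003144) and NF-kB target genes (0.01566). The 16 lists called by camera became 2 with an estimated correlation, 3 with fry by direction, 8 in the 4 samples alone (cause not tested) and 0 by exact permutation of list means, in which 5 had an unadjusted p under 0.05. There the plasma-cell, histone and germinal centre lists reached the smallest p possible (0.00476, adjusted p = 0.0571), which passes only if at least 4 lists reach it. Without any 1 sample 11 to 18 lists were called. Glycolysis lost its call by camera in the 4 samples alone (median -0.003213, adjusted p = 0.908, and from 0.00136 to 0.908 over its settings). Camera's direction changed there without a call, and the cause was not tested. Of 57 named genes past the threshold all kept their sign in every setting, 23 passed without any 1 sample and 25 in at most 4 of those 10 fits. Where the groups do not overlap, as in most calls, the sign is largely fixed in advance, so its tally is no test. Leaving that block aside, 1174 of 1472 values of named genes stayed on their side of the threshold and 297 lost the call. At these depths, sample numbers and dispersions together, 26% of simulated 1.5-fold changes were recovered.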

Other observations

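The tests on the surroundings and paralogues of DDX3X, on small non-coding RNAs, on S-phase genes, on chromosome 10, on the division into 2 sets and on zinc-finger genes, and the exact permutation of list means, were chosen after the results were seen, the removal of length and GC trends after the data but before its result were seen, and the other tests of this part before. The 10 samples can be divided into 6 and 4 in 210 ways, of which 100 were drawn. For the 419 genes changed, 1 of the 100, the real division, gave as many, and the highest count among the others was 2. For the 122 genes changed at least 2-fold it was again 1 of 100, with a highest other count of 1. Both counts exceed those of a chance division only if the 10 samples are independent. Most divisions drawn break up the pairs of samples that lay closest, so they cannot exclude chance differences among clones. The division into the 4 samples that stand apart and the other 6 was not among those drawn. It keeps the closest pairs whole and gave 1961 genes, more than the real division. This points to a structure of the samples, but the division was made from these same levels. For the 16 gene lists called by camera with its preset correlation, 35 of the 100 divisions gave as many and the highest of the others gave 26, so chance cannot be excluded for the number of lists. The plasma-cell and histone lists also passed with an estimated correlation (adjusted p = 0.0341 and 0.0488). In the exact permutation of their means both reached the smallest p possible (0.00476, adjusted p = 0.0571), which adjustment over 36 lists lets pass only if at least 4 lists reach it, so that test does not argue against them.

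The 419 calls were set against 3 differences between the libraries. With trends of gene length and GC content removed from each library, 86.2% of them were called again in their direction. With 1 surrogate variable, which takes up the division of the samples that runs across both genotypes, 100% were. That variable was estimated with genotype in the model and takes high and low values in both genotypes. Adding it mainly removes spread within the groups, so this fit could hardly lose calls and decides little. If the genotypes differed in the copy number of chromosome segments, neighbours would move together, but over 404 called genes the median ratio of the neighbours' change to the gene's own was 0.0389 (95% bootstrap bounds 0.0294 to 0.0544). That median covers the calls as a whole and cannot exclude a segment that holds a minority of them. ZNF93 and ZNF486, both higher, start at 19900913 and 20167228 on chromosome 19. A difference between clones that arose by chance during cloning stays open, since the labels do not say how many clones the samples represent.

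The higher level of DDX3X was set against 2 technical explanations. A gain of the region would raise its neighbours, and the 9 other tested genes within 2 Mb had a median log2 fold change of 0.10 (0.0978; bounds -0.27 to 0.21), below the 1.15 of DDX3X. Reads that moved to DDX3X from its paralogue or pseudogenes would show as a difference there, and the summed difference over those 4 genes was 0.0330% of the rise. Reads of those genes counted only at DDX3X in both groups would not show there, so this test cannot exclude them. With a gain that reaches the neighbours excluded as the whole cause, what raised the level stays open. A gain of DDX3X alone was not tested, since USP9X ends at 41236579 and CASK starts at 41514934. No biological explanation was tested.

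The fall of canonical histone transcripts was set against 3 explanations. Less carry-over of RNA without a poly(A) tail would lower other such RNAs, but 104 small non-coding RNAs had a median log2 fold change of 0.28 (bounds 0.19 to 0.43), the opposite direction. Some of these lie within other genes on the same strand, as SNORA48 does in EIF4A1, so their reads may come from the host transcript. The snoRNA host genes had a like median of 0.27, so this test cannot exclude less carry-over. Reads moving among near-identical copies would leave the sum unchanged, but the summed count over 47 histone genes was -0.95 on the log2 scale (R475C minus wild-type), with no overlap between the groups. A smaller share of cells in S phase might lower histones and G1/S genes alike. The mean log2 CPM of the G1/S list was lower in R475C (exact permutation p = 0.0714), which did not pass and does not show equal levels, so a smaller S-phase share cannot be told apart from a change in histone transcripts alone.

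The 4 samples that stand apart within their groups may be clones with an altered karyotype. When the samples were divided on the genes of all chromosomes but 10, the same 4 were found, and the 515 genes of chromosome 10 then differed between the 2 sets by a median log2 of 0.78 in wild-type and 0.77 in R475C. In windows of 20 Mb the difference ran from 0.58 to 1.02 in both genotypes from 40 Mb onward, while in the window from 0 Mb it was 0.05 in both and in that from 20 Mb it was -0.10 in wild-type and -0.12 in R475C. Chromosome 21 differed by 0.57 and 0.66, and chromosome 3 from 120 to 140 Mb by 0.52 and 0.55. A candidate explanation is a difference in copy number of these segments among clones, present in both genotypes. The 4 samples make up a larger share of the R475C group than of the wild-type group, so the genotype contrast carries part of this division. Genes of chromosome 10 had a median log2 fold change of 0.13, R475C over wild-type, and 3 of the 515 (0.58%) were called. No DNA was measured, and the separate origin of the 4 samples was not tested.

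Some genes with small p lie outside the lists and were chosen after their values were seen. RBM47, an RNA-binding protein, fell from 14.6 ± 1.82 to 3.49 ± 0.402 CPM (log2 fold change -2.06, SE 0.15, adjusted p = 1.43e-04). FUT8, the fucosyltransferase of N-glycan cores, fell from 84.4 ± 5.91 to 41.3 ± 4.35 CPM (-1.03, SE 0.09, adjusted p = 4.22e-04), as did FUT8-AS1 on the other strand (-1.19), and PARP6 rose from 53.6 ± 4.83 to 103.9 ± 6.55 CPM (0.95, SE 0.09), as did an unnamed locus that it overlaps, ENSG00000273025 (0.87). The call of FUT8-AS1 held in 3 of the 10 fits that left out 1 sample. AGO2, the slicing Argonaute protein, rose from 124 ± 13.2 to 221 ± 30.0 CPM (0.84, SE 0.11, adjusted p = 0.00317). In the BCL2-family list HRK (1.61, SE 0.43, adjusted p = 0.0741, groups overlapping) and PMAIP1 (-0.46, SE 0.11, adjusted p = 0.0512) passed edgeR's test only when adjusted over that list alone, while DESeq2, 1 surrogate variable and the 2 sample sets as covariate called both over all genes and limma-voom called PMAIP1 alone. Because zinc-finger genes led the rises, all 421 tested genes with ZNF symbols were counted: 12 were higher and 0 lower by edgeR (67 and 8 at an unadjusted p under 0.05, 30 and 3 called by DESeq2), or 2.85% higher against 1.59% of 12205 other protein-coding genes, which did not pass a two-sided Fisher exact test (p = 0.0732). Of all 17045 genes tested, 2951 had an unadjusted p under 0.05 and DESeq2 called 1156.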
